A study of Mus musculus with 13 samples.

How the data were processed

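The series profiled chromatin of cultured mouse (C57BL6) olfactory basal cells, sorted from the adult olfactory epithelium for the surface receptor c-KIT and grown as adherent lines. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for RING1B and CBX8, both components of Polycomb repressive complex 1 (PRC1), and for the histone marks H3K27me3 and H3K27ac. Each antibody has 2 libraries, and 5 inputs belong to the series. The 8 ChIP libraries each have a peak list; the inputs have none of their own here and enter only through the fold values. Per the labels, the libraries come from 3 cell lines. Line 1 at passage 12 gave H3K27me3 replicate 1 and RING1B replicate 1. Line 2 gave H3K27me3 replicate 2 at passage 11, RING1B replicate 2 and CBX8 replicate 1 at passage 19, and H3K27ac replicate 1 at passage 13. Line 3 at passage 14 gave CBX8 replicate 2 and H3K27ac replicate 2. A replicate number therefore does not mark the same culture across antibodies, and antibody and culture cannot be separated for most pairs of libraries.

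Per the submitters' processing notes, bcl2fastq 2.17, Trim Galore 0.4.3, BWA 0.7.12 and MACS2 2.1.1.20160309 were used with genome build mm10. The options, the treatment of duplicate reads and the control used for each list are not given in the sources used here. Each list was taken as the peaks of a single library, as the labels give it, with the authors' annotation of each peak to a transcript and gene. Peak names in some lists hold the word combined, whose meaning is not stated, so pooling of libraries in those lists cannot be ruled out. The lists for the histone marks have the form of MACS2 broad peaks, with q-values up to 0.1, and the lists for RING1B and CBX8 that of narrow peaks, with q-values up to 0.01. The value per peak is the authors' fold enrichment over the control. The authors' −log10 q-value per peak was used only for a stricter threshold, and their −log10 p-value was not used. The deposited score column, which follows the q-value, was not used. The lists hold no read counts, so sequencing depth is unknown and no interval that needs it is given. A fold is the authors' own value for that peak in that library, and folds were used to rank or describe peaks within a list. Fold values of narrow and broad lists are on different scales. The absence of a peak means that none was listed, not that the fold was 0.

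Peaks on chromosomes 1 to 19 and X entered the comparisons. Shared regions of an antibody are the bases under a peak of both replicates. Regions overlapped when they had at least 1 bp in common. The overlap expected from position alone came from 1000 circular shifts of a list along each chromosome, starting from 3 Mb. The smallest p these shifts can give is 0.000999 in a one-sided test and 0.002 in a two-sided test. Shifts preserve the spacing of peaks but not their preference for genes or open chromatin, so a low p from this permutation test shows more overlap than at random positions.

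Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, which gives no strand. The strand was taken from the deposited annotation by Entrez gene ID, which left 19154 of 21631 protein-coding genes (88.5%) as the background. The strand is known only for genes that the authors' annotation assigned to some peak, so the background leaves out many genes far from any peak, among them 570 of 1106 olfactory receptor genes. The start of a gene is the 5′ end of its RefSeq extent, so a gene has a single start here and internal promoters were not used. A gene was called a target of an antibody when a peak of each replicate overlapped the 2 kb on either side of its start, and a PRC1 target when it was a target of both RING1B and CBX8. The window of 14.9% of the genes overlaps that of another gene, and such genes can share a peak.

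Before the data were examined, 23 gene lists were fixed, together with the definition of a target, the tests and the rule for genes named in the text. The lists cover Hox genes, other developmental regulators, the olfactory neuron lineage, other cell types of the epithelium or a culture, signalling, Polycomb, cell cycle and housekeeping genes, and chemosensory receptors. The named genes are up to 4 PRC1 targets and up to 4 H3K27ac targets without PRC1 of each list, with the highest fold in the weaker replicate, the 10 genes with the highest fold of each antibody, 18 genes fixed by name, and genes of the 5 widest H3K27me3 regions. Some genes that these rules pick are not reported here, 1 of the 18 among them, while all counts and tests include them. Other genes named in the text were chosen after their values were seen. Lists were compared with all other background genes by Fisher's exact test, one-sided for more targets and, separately, for fewer, with Benjamini-Hochberg adjustment over the 23 lists. List tests of RING1B targets, with or without CBX8, were not among the tests fixed beforehand and are given for some lists only. Pairs of gene sets were compared by a two-sided Fisher's exact test, with a Wald 95% interval of the odds ratio. Genes are not independent replicates, least of all neighbours under a single broad peak, so these p-values are too small to be read as replicate error. The spread between libraries is given by the value of each replicate.

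Interval functions gave the same overlaps as a direct count on 300 regions. In the shift test of RING1B replicate 1 against CBX8 replicate 2, 3% of 100 unrelated pairs of lists had p under 0.05. These pairs were made by the same kind of shift and tested with 100 shifts each, so a low rate follows from the design. It does not cover real lists that share a preference for genes or open chromatin. Planted overlaps of 10, 40 and 80% for 7566, 7518 and 7297 regions were recovered as 12.6, 40.0 and 79.2%, the first including overlap by position alone. For the list test of PRC1 targets over 19154 genes, all lists planted at 50% targets against 4.3% were recovered (100%), and 0.444% of 900 tests of lists with nothing planted were called. Smaller shares were not planted. Targets were drawn independently, so neighbouring genes that share a peak were not imitated. The alternatives tried were a stricter q-value, a larger overlap, lists of equal length, other definitions of shared regions, windows of 500 bp and 5 kb, the nearest gene at any distance, each replicate left out, and libraries of the same culture. After the data were seen, 4 more were added: genes without a strand counted at either end, the authors' annotation within 2 kb, every transcript start named in the files, and removal of peaks touching regions listed in all 8 libraries. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.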

Results

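Adult olfactory basal cells renew the sensory neurons of the nose, and the c-KIT-sorted lines studied here are their precursors in culture. The series asked which genes PRC1 occupies in these precursors, by mapping RING1B, the catalytic ubiquitin ligase of PRC1, CBX8, a chromodomain subunit that can bind H3K27me3, H3K27me3 itself, the mark set by Polycomb repressive complex 2, and H3K27ac, a mark of active promoters and enhancers. The lists held 68898 and 101129 peaks for H3K27me3 (replicates 1 and 2), 7578 and 32918 for RING1B, 9926 and 77417 for CBX8, and 123155 and 112175 for H3K27ac. They covered 80.7 and 188 Mb for H3K27me3, 3.84 and 11.9 Mb for RING1B, 3.50 and 18.4 Mb for CBX8, and 166 and 151 Mb for H3K27ac. Read depth is unknown. With 2 libraries per antibody, each value below is given for both or for what both have in common.

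RING1B had the largest share of its peaks at gene starts. Of its peaks, 62.1 and 47.2% lay within 2 kb of the start of the transcript named in the authors' annotation (mean 54.6% ± 10.6, SD, n = 2), against 30.6 and 13.0% for CBX8 (21.8% ± 12.5, n = 2), 15.2 and 16.3% for H3K27ac (15.8% ± 0.781, n = 2) and 11.6 and 9.13% for H3K27me3 (10.4% ± 1.76, n = 2). Peaks in distal intergenic sequence made up 47.8 and 53.5% of the H3K27me3 lists and 28.2 and 30.3% of the H3K27ac lists. No test was made with 2 libraries per antibody, and the 2 CBX8 libraries differed from each other by more than the CBX8 mean differed from that of H3K27ac.

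The first comparison asked whether the libraries of an antibody mark the same places. Of the shorter list's peaks, 82.7% overlapped the other replicate for RING1B, 70.3% for H3K27ac, 66.7% for H3K27me3 and 54.0% for CBX8. At shifted positions these shares were 1.18, 12.3, 12.5 and 1.95% (permutation p = 0.000999 for each, the smallest the 1000 shifts allow, one-sided). The longer lists of RING1B and CBX8 held many peaks that the other replicate lacked: 17.5% of the peaks of RING1B replicate 2 and 5.72% of those of CBX8 replicate 2 overlapped replicate 1. In CBX8 replicate 2 the median fold was 8.46 for overlapping and 4.78 for other peaks, and in RING1B replicate 2 it was 7.67 and 4.49. The bases common to both replicates formed 47373 regions for H3K27me3, 6702 for RING1B, 5502 for CBX8 and 84335 for H3K27ac.

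RING1B regions that both CBX8 libraries shared lay under H3K27me3, and most of the others lay under H3K27ac. A region or gene is called without CBX8 here when it lacks a peak common to both CBX8 libraries, and it can hold one of a single library. CBX8 overlapped 43.5% of the RING1B regions, against 0.195% ± 0.0992 (SD of shifts) at shifted positions (permutation p = 0.000999, one-sided). Of these 2913 PRC1 regions, 95.3% overlapped H3K27me3, against 4.18% ± 0.957 at shifted positions (permutation p = 0.000999, one-sided). H3K27ac overlapped 10.4% of them, against 7.26% ± 1.10 (permutation p = 0.018, two-sided). This small excess of H3K27ac did not hold with stricter peaks (4.27%, permutation p = 0.806) or when 50% of the region had to be covered (5.81%, p = 0.328). Removing peaks that touch regions listed in all 8 libraries, chosen after the data were seen, gave 3.37% (7.29% shifted, permutation p = 0.00995), but these regions hold RING1B, CBX8 and H3K27ac by definition, so the fall follows in part from the removal and does not count against the excess. Among the 3789 RING1B regions without CBX8, 39.2% overlapped H3K27me3 (3.19% shifted) and 63.2% overlapped H3K27ac (5.66% shifted), each with permutation p = 0.002, two-sided. H3K27me3 and H3K27ac regions avoided each other: 2.96% of the H3K27me3 regions overlapped H3K27ac, against 8.51% ± 0.444 at shifted positions (permutation p = 0.002, two-sided). The single libraries moved several of these values. CBX8 overlapped 64.5% of the RING1B regions without CBX8 replicate 1. Without RING1B replicate 1, CBX8 overlapped 11.1% of them and H3K27ac 19.3% of the PRC1 regions, and the latter was 16.4% without CBX8 replicate 1 and 18.4% without H3K27ac replicate 1. The H3K27ac share of H3K27me3 regions was 6.94% (8.28% shifted) without H3K27me3 replicate 2, much closer to the shifted value, and 6.14 and 6.67% (11.3 and 12.5% shifted) without H3K27ac replicates 1 and 2. RING1B covered a small part of the methylated regions, 3.62% of them by number (0.381% shifted, permutation p = 0.002, two-sided).

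**Figure D1:**
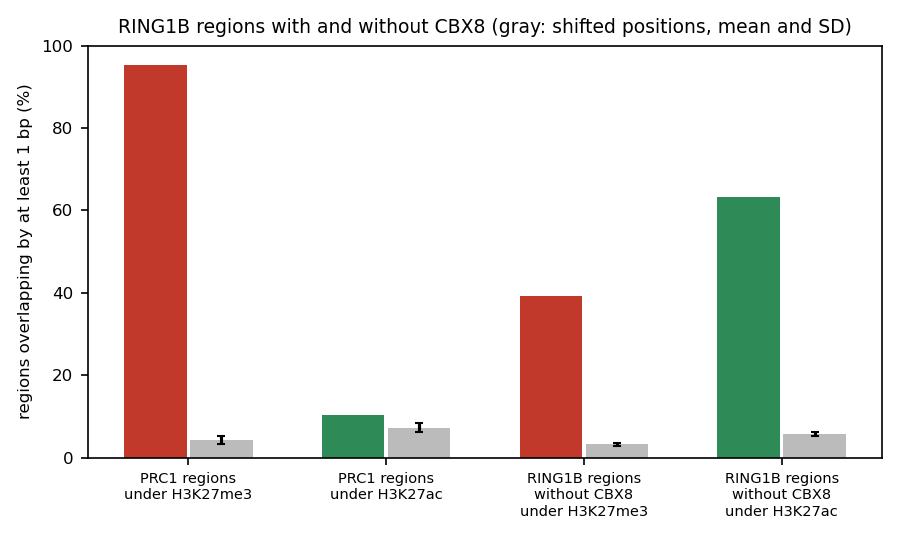
Percent of RING1B regions with CBX8 (PRC1 regions, 2913) and without CBX8 (3789) that overlapped H3K27me3 (red) or H3K27ac (green) regions by at least 1 bp; gray bars give the mean over 1000 shifts, with their SD. PRC1 regions were 95.3% under H3K27me3, and RING1B regions without CBX8 were 63.2% under H3K27ac.

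PRC1 occupied the promoters of 818 of 19154 genes. Among the highest RING1B folds in the weaker replicate were those at Igf2bp3 (76.2 and 85.2), Tlx3 (69.7 and 80.6), Tlx2 (63.1 and 73.2), Nkx3-2 (60.9 and 70.1), Tal1 (60.6 and 70.3), Gfi1 (58.9 and 75.5), Nkx6-2 (51.3 and 65.6), Foxb2 (49.6 and 62.5) and Shisa3 (59.5 and 48.6), with the values of replicates 1 and 2 in that order. Of these genes, Igf2bp3 encodes an RNA-binding protein and Shisa3 a membrane protein; the others named encode transcription factors. CBX8 was highest at Tlx3 (102 and 98.2), Tlx2 (97.8 and 96.7) and Igf2bp3 (118 and 92.3), followed by Tal1, Cyp24a1 and Pfdn4, which share a peak, Hoxb2, Foxb2, Sp9 and Nkx3-2. H3K27me3 was highest at Nkx2-4 (7.35 and 7.82), Foxd1 (7.23 and 8.32), Hoxa9 (7.19 and 8.47), Gfi1, Hoxa10, Hoxa11, Hoxd11, Hoxd10, Nkx2-3 and Aldh1a2, the gene of a retinoic acid synthesis enzyme. H3K27ac was highest at Ei24 (30.3 and 34.2), Rnf169 (29.2 and 31.8), Map3k20, Akirin2, Tsc22d2, Bmpr1a, Rnf19a, Commd3, Ier5 and Nckap1, none of them a PRC1 target.

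RING1B was found at 2694 promoters in both replicates (2848 and 9370 in each alone), CBX8 at 1149 (1497 and 4850), H3K27me3 at 4249 (5325 and 6084) and H3K27ac at 12229 (12776 and 13070). Of the RING1B targets, 30.4% were CBX8 targets, against 2.01% of the other genes (odds ratio 21.2, 95% interval 18.5 to 24.4, Fisher's exact test). The number of PRC1 targets rested on CBX8 replicate 1 in particular: without it, 1476 genes qualified, of which 52.2% had H3K27ac, so many RING1B targets without CBX8 by the definition used hold a CBX8 peak of replicate 2.

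PRC1 target genes were methylated and, by the definition used, mostly not acetylated. H3K27me3 was present at 759 of the 818 (92.8%), against 19.0% of the other genes (odds ratio 54.7, 95% interval 41.9 to 71.5). With stricter peaks, which left 805 and 2051 H3K27me3 peaks, this share was 49.5%. H3K27ac was present at 273 (33.4%), against 65.2% (odds ratio 0.267, 95% interval 0.230 to 0.310, p = 5.96e-73, two-sided Fisher's exact test). The share was 11.1% (against 58.5%) with stricter peaks and 25.8% without peaks touching regions listed in all 8 libraries, which takes out promoters with both by construction. Without CBX8 replicate 1 it was 52.2%, so most PRC1 targets were then acetylated. By combination, 539 PRC1 targets had H3K27me3 without H3K27ac, 220 had both marks, 53 had H3K27ac alone and 6 had neither. The 1876 RING1B targets without CBX8 differed from the PRC1 targets in both marks: 26.5% had H3K27me3 (odds ratio of PRC1 against these genes 35.6, 95% interval 26.8 to 47.3) and 89.4% had H3K27ac (odds ratio 0.0594, 95% interval 0.0483 to 0.0731). H3K27me3 targets had H3K27ac in 29.3% of cases, against 73.7% of the other genes (odds ratio 0.148, 95% interval 0.137 to 0.159). When each peak was given to the nearest gene at any distance, the order for H3K27ac at PRC1 targets turned, to 80.8% against 77.8%.

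The next comparison asked which gene groups PRC1 occupies, as the series set out to find targets of the neuron lineage. Transcription factors of the olfactory neuron lineage were PRC1 targets in 14 of 25 cases (56.0%, against 4.20% of the other genes, adjusted p = 1.33e-12, Fisher's exact test). They included Neurog1 (RING1B 14.5 and 9.33, CBX8 7.42 and 33.1), Neurog2 (RING1B 41.4 and 57.6, CBX8 54.6 and 59.6), Neurod1 (RING1B 7.88 and 7.22, CBX8 9.39 and 18.6) and Neurod2 (RING1B 42.2 and 45.1, CBX8 46.0 and 66.6). Nhlh2 (RING1B 34.3 and 45.9) and Ebf1 (RING1B 31.7 and 51.2, CBX8 51.9 and 73.9), factors of differentiating neurons, and Lhx2 (RING1B 15.5 and 30.1), a factor needed for olfactory receptor expression, were also among them. H3K27me3 lay at 20 of the 25 (exact adjusted p = 7.55e-09) and H3K27ac at 5, fewer than among the other genes (20 against 63.9%, adjusted p = 3.06e-05): Sox4 (24.6 and 26.7), Runx1 (9.77 and 8.73), Sox11, St18 (2.87 and 2.88) and Ebf4.

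Hox genes and other developmental transcription factors had the highest shares of PRC1 targets. PRC1 was at 36 of 39 Hox genes (92.3%, adjusted p = 4.39e-45, Fisher's exact test), with RING1B of 42.6 and 74.6 and CBX8 of 82.6 and 81.7 at Hoxb2, RING1B of 40.9 and 52.8 at Hoxa13, 37.4 and 35.1 at Hoxa11 and 34.8 and 59.2 at Hoxb8. All 39 had H3K27me3 and 2 had H3K27ac. Of 61 other developmental factors, 36 were PRC1 targets (59.0%, exact adjusted p = 8.64e-33), with high RING1B at Nkx3-2, Tbx15 (46.5 and 62.9), Lhx8 (49.9 and 46.4) and Otx2 (41.7 and 58.1). The olfactory lineage factors had a similar share (56.0%), so a high share was not particular to that lineage. Members without PRC1 and with strong H3K27ac included Irx5 (20.5 and 15.5), Foxa1 (19.1 and 12.3) and Irx3 (11.7 and 12.1). At Irx5, CBX8 had a fold of 52.3 in replicate 2 and no peak in replicate 1.

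**Figure D2:**
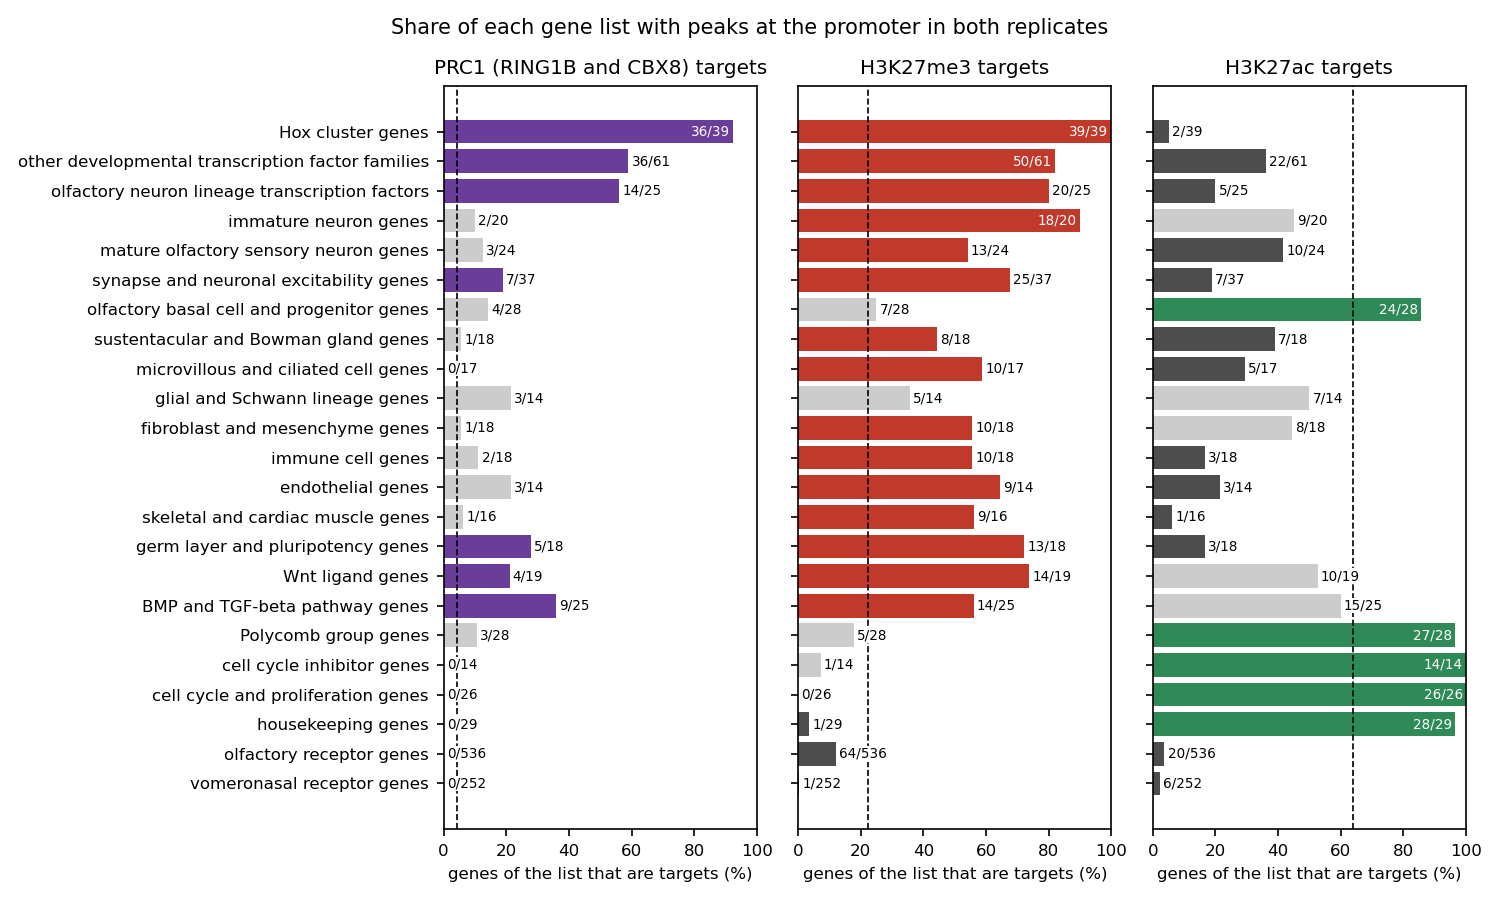
Percent of each gene list with PRC1 (left), H3K27me3 (middle) or H3K27ac (right) at the promoter in both replicates; labels give targets and measured genes, dashed lines the share of all 19154 genes. Coloured bars have more targets than other genes and dark gray bars fewer, at an exact adjusted p under 0.05, and light gray bars neither. Hox genes were PRC1 targets in 36 of 39 cases. Cell cycle genes were PRC1 targets in 0 of 26 cases, which did not pass the test for fewer.

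Genes of neurons themselves had H3K27me3 more often than other genes. Immature neuron genes had H3K27me3 at 18 of 20 promoters (90%, against 22.1% of the other genes, adjusted p = 1.50e-09, Fisher's exact test). Among them were Gap43 (3.01 and 2.49), Tubb3 (3.82 and 3.83) and Stmn2 (3.47 and 3.98), which encode a growth cone protein, neuronal tubulin and a microtubule regulator. PRC1 was at 2 of the 20, Ncam1 (RING1B 5.99 and 8.80) and Dpysl5 (5.57 and 19.0), a share that did not pass the test (exact adjusted p = 0.344). It passed with the 5 kb window, the nearest gene, the authors' annotation or all named transcript starts, and without CBX8 replicate 1. RING1B in both replicates, with or without CBX8, was at 7 of the 20 (35.0 against 14.0%, adjusted p = 0.0451, Fisher's exact test, not planned). H3K27ac was at 9, the strongest at Nrp1 (19.5 and 19.5), Map2 (8.64 and 6.27), Mapt (5.36 and 5.40) and Kirrel3 (6.15 and 4.13). Synapse and excitability genes had H3K27me3 in 25 of 37 cases (exact adjusted p = 2.07e-08) and PRC1 in 7 (18.9%, adjusted p = 0.00325), including the GABA synthesis genes Gad2 (RING1B 32.2 and 24.8) and Gad1 (20.7 and 22.4), and Scn1a (12.9 and 12.0). RING1B in both replicates, with or without CBX8, did not pass for this list (8 of 37, 21.6 against 14.1%, adjusted p = 0.292, Fisher's exact test, not planned). H3K27ac was at 7 of the 37, fewer than among other genes (18.9 against 63.9%, adjusted p = 1.58e-07, Fisher's exact test). The high folds among these 7 were at Rims2 (20.6 and 22.0), Vamp2 (9.38 and 9.82), Dlg2 and Dlg4. Mature olfactory sensory neuron genes had H3K27me3 in 13 of 24 cases (exact adjusted p = 0.00161, a call lost with stricter peaks), PRC1 in 3 (Pde4a, Gnal and Pde1c, adjusted p = 0.169) and H3K27ac in 10, fewer than among other genes (adjusted p = 0.0423). Gnal, the olfactory G protein subunit, had RING1B of 7.51 and 10.9 and CBX8 of 4.94 and 8.09, while Ric8b (13.9 and 13.4), Cnga4 (13.4 and 12.8), Adcy3 and Cdhr1 had H3K27ac and no PRC1. Omp, the marker of mature olfactory neurons, had weak H3K27ac (3.61 and 3.65) and no H3K27me3. Within the H3K27me3 targets, a comparison added after the data were seen gave PRC1 at 11.1% of the immature neuron genes against 17.9% of the other methylated genes (adjusted p = 1), at 23.1% of the mature neuron genes against 17.8% (adjusted p = 1), at 28.0% of the synapse genes against 17.8% (adjusted p = 0.432) and at 65.0% of the lineage transcription factors against 17.6% (adjusted p = 2.43e-05, two-sided Fisher's exact test).

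Genes of basal cells, the cell cycle, Polycomb and housekeeping were acetylated. H3K27ac was at 24 of 28 basal cell and progenitor genes (85.7%, against 63.8% of the other genes, adjusted p = 0.0455, Fisher's exact test), a call lost with stricter peaks, the 5 kb window or the nearest gene. High folds were at the BMP receptor gene Bmpr1a (27.8 and 29.9), Sox2 (23.6 and 23.9) and Itgb1 (21.9 and 19.6). Sox2 was also a RING1B target (4.74 and 6.40), without CBX8 or H3K27me3. The keratins of horizontal basal cells, Krt5 (11.4 and 10.5) and Krt14 (9.61 and 8.0), were acetylated in both replicates, and Trp63, the master regulator of those cells, had a weak H3K27ac peak in replicate 1 (2.37) and none in replicate 2 at the outermost start, the only start used. PRC1 was at 4 of the 28, Pax6 (RING1B 24.2 and 23.8), Mycn (17.3 and 13.5), the stem cell receptor gene Lgr5 (13.8 and 12.0) and Fgfr2 (4.15 and 8.58), a share that did not pass the test (exact adjusted p = 0.0688) but passed without CBX8 replicate 1. RING1B in both replicates, with or without CBX8, was at 11 of the 28 (39.3 against 14.0%, adjusted p = 0.00292, Fisher's exact test, not planned). Kit, which encodes the receptor used for the sort, carried H3K27me3 (4.70 and 4.05) and RING1B (10.4 and 5.12) in both replicates, with CBX8 (9.56) and weak H3K27ac (2.45) in replicate 2 alone. Pax6 had no H3K27ac peak at its start in replicate 1 and a fold of 12.5 in replicate 2; these libraries come from lines 2 and 3.

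All 26 cell cycle genes had H3K27ac (exact adjusted p = 0.000195), for example Cdk6 (23.1 and 22.2), Mcm3 (20.6 and 13.5), Mki67 (16.6 and 13.0) and Cdk2 (12.3 and 13.3). None was a PRC1 target, a share not different from the 4.28% of other genes (p = 0.627, two-sided Fisher's exact test, unadjusted). All 14 cell cycle inhibitor genes had H3K27ac too (exact adjusted p = 0.0107), among them Rbl1 (20.9 and 20.3), Cdkn1b (19.3 and 16.0), Gadd45b and Cdkn2b (15.0 and 15.7). Cdkn2a, a classical Polycomb target that limits self-renewal, had H3K27ac of 17.8 and 13.2, no H3K27me3 and no CBX8 peak at its outermost start. That was the only start used, and the rest of the locus was not examined. Of 28 Polycomb group genes, 27 had H3K27ac (exact adjusted p = 0.000448), with high folds at Eed (19.4 and 21.1), Ezh2 (17.4 and 17.8), Aebp2 (18.5 and 17.2), Rybp (17.8 and 16.7) and Rnf2 (15.6 and 15.7), the gene of RING1B. PRC1 was at 3 of its own group's genes (exact adjusted p = 0.222, passing with the nearest gene and without CBX8 replicate 1): Bmi1, Cbx8 and Cbx2. RING1B in both replicates, with or without CBX8, was at 13 of the 28 (46.4 against 14.0%, adjusted p = 0.000222, Fisher's exact test, not planned). Bmi1 (RING1B 16.4 and 25.9, CBX8 23.7 and 23.2, H3K27ac 14.1 and 14.8) and Cbx8 (RING1B 11.8 and 28.3, CBX8 18.9 and 23.6, H3K27ac 9.78 and 10.3) also carried H3K27me3. Housekeeping genes had H3K27ac in 28 of 29 cases (exact adjusted p = 0.000443), such as Hsp90ab1 (19.9 and 20.7), Rpl5, Rps6, Rpl7 and Actb (12.2 and 9.23). Given to the nearest gene, H3K27ac peaks left 1 list, Polycomb group genes, above the other genes, and with the authors' annotation the cell cycle inhibitor and housekeeping lists dropped out.

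**Figure D3:**
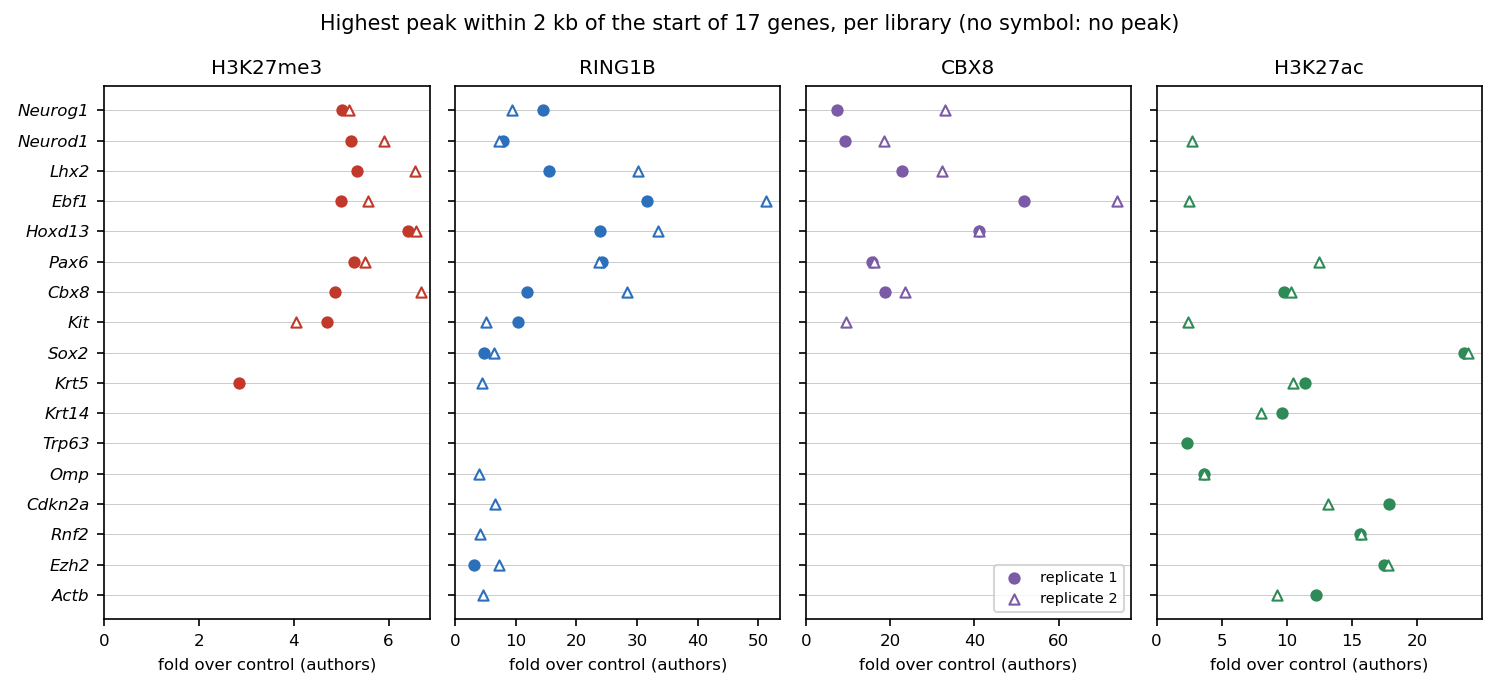
Highest fold over control, as the authors' lists give it, of a peak within 2 kb of the start of 17 genes fixed by name, for replicate 1 (circles) and replicate 2 (triangles) of each antibody; no symbol means no peak. Neurog1, Neurod1, Lhx2, Ebf1, Hoxd13, Pax6 and Cbx8 had H3K27me3, RING1B and CBX8 in both replicates. Sox2 had H3K27ac of 23.6 and 23.9 and RING1B of 4.74 and 6.40, without H3K27me3 or CBX8.

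Some signalling and early developmental genes were PRC1 targets, a minority in each list. PRC1 was at 9 of 25 BMP and TGF-beta pathway genes (36.0%, adjusted p = 2.87e-06, Fisher's exact test), among them Gdf6 (RING1B 18.3 and 28.5), Gdf7 (13.8 and 19.0), Bmp7 (10.2 and 13.4) and the BMP antagonist gene Nog (8.23 and 11.5), whereas Fst (14.2 and 15.0), Smad7, Smad6 and Tgfb1 had H3K27ac without PRC1. Of 19 Wnt genes, 4 were PRC1 targets (exact adjusted p = 0.0252), Wnt1 (RING1B 12.9 and 21.7), Wnt16, and the neighbours Wnt3 and Wnt9b, which share a peak; 14 had H3K27me3 (adjusted p = 9.67e-06) and 10 had H3K27ac (52.6%, adjusted p = 0.292 for fewer), led by Wnt7b (13.0 and 12.6), Wnt7a, Wnt9a and Wnt5a. Germ layer and pluripotency genes were PRC1 targets in 5 of 18 cases (exact adjusted p = 0.00325): Eomes (38.3 and 55.7), Sox1, Fgf4, Sox7 and Fgf5. For RING1B in both replicates, with or without CBX8, the list did not pass (5 of 18, 27.8 against 14.1%, adjusted p = 0.249, Fisher's exact test, not planned). Within the H3K27me3 targets, in the comparison added after the data were seen, PRC1 was at 28.6% of the Wnt genes against 17.8% of the others (adjusted p = 0.520), 38.5% of the germ layer genes against 17.8% (adjusted p = 0.216) and 64.3% of the BMP and TGF-beta genes against 17.7% (adjusted p = 0.000691, two-sided Fisher's exact test). With a window of 500 bp the BMP and TGF-beta list and the Wnt list no longer passed for PRC1. Nog and Bmp7 carried all 4 features, with H3K27ac of 6.62 and 8.61 and of 6.42 and 7.01.

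Most lists for other cell types of the epithelium or of other tissues had more H3K27me3 targets than the other genes. H3K27me3 was at 9 of 14 endothelial, 10 of 17 microvillous and ciliated, 9 of 16 muscle, 10 of 18 immune, 10 of 18 fibroblast and 8 of 18 sustentacular and gland genes (adjusted p = 0.00197, 0.00244, 0.00519, 0.00373, 0.00373 and 0.0453, Fisher's exact test). Glial genes had it in 5 of 14 cases (exact adjusted p = 0.260). Several of these calls depended on the settings. With stricter peaks the sustentacular, fibroblast, immune, microvillous, mature neuron and BMP lists no longer passed for H3K27me3, and at 500 bp the sustentacular, fibroblast and immune lists did not. The sustentacular list was also lost without H3K27me3 replicate 2 and with all named transcript starts. With the nearest gene the Hox, sustentacular, fibroblast and muscle lists were lost and the glial list passed, and the authors' annotation exchanged the Hox list for the glial one. PRC1 was at Erg, Flt1 and Sox17 of the endothelial list and at Foxd3, Slc1a3 and Frzb of the glial list, in each 3 of 14 genes (21.4 against 4.26%, exact adjusted p = 0.0507). Both lists passed with stricter peaks, the nearest gene, the authors' annotation, genes without a strand counted, and regions listed in all 8 libraries removed, and the glial list also at 500 bp, at 5 kb and with all named transcript starts. PRC1 was further at Ikzf3 and Ikzf1 of the immune list (exact adjusted p = 0.315), Pdgfra among fibroblast, Lgi1 among sustentacular and Hand2 among muscle genes (adjusted p = 0.736 each), and at none of the 17 microvillous and ciliated genes. H3K27ac was at 7 of 18 sustentacular, 5 of 17 microvillous, 3 of 18 immune, 3 of 14 endothelial and 1 of 16 muscle genes. Each share was below that of other genes (adjusted p = 0.0482, 0.00858, 0.000141, 0.00346 and 1.14e-05 for fewer, Fisher's exact test). The fibroblast (8 of 18) and glial (7 of 14) lists did not pass (exact adjusted p = 0.112 and 0.292 for fewer). Acetylated members included Sox9 (17.7 and 16.5), Aqp5 (19.1 and 16.0), Krt18 (13.0 and 13.8) and Krt8 (11.4 and 11.5), which sustentacular and gland cells express, and Fn1, Prrx1, Twist1 and Sparc of the fibroblast list. At Twist1, RING1B (17.9 and 7.22) and H3K27me3 (4.89 and 3.34) were present with H3K27ac (15.5 and 8.86). Olfactory receptor genes were PRC1 targets in 0 of 536 cases (exact adjusted p = 1.13e-09 for fewer), H3K27me3 targets in 64 (11.9 against 22.5%, adjusted p = 5.27e-09 for fewer) and H3K27ac targets in 20 (3.73 against 65.6%, adjusted p = 1.79e-200 for fewer). Of 252 vomeronasal receptor genes, 0 had PRC1, 1 had H3K27me3 and 6 had H3K27ac (exact adjusted p = 0.000179, 3.76e-25 and 3.44e-99 for fewer).

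Of the 5 widest H3K27me3 regions, 2 lay over Hox clusters. On chromosome 18, from 60975283 to 61071304 (mm10), a region of 96022 bp covered Slc6a7 and Cdx1 and part of Pdgfrb and Camk2a, with none of their promoters a target of RING1B in both replicates. On chromosome 11, from 96268162 to 96357637, a region of 89476 bp covered Hoxb2 to Hoxb9, and every start in it was a PRC1 target. No protein-coding gene of the background lay in the third, on chromosome 8 from 123537449 to 123624532. The others covered Hoxc6, Hoxc8, Hoxc9 and Hoxc10 (chromosome 15, 102959522 to 103003491, touching a region listed in all 8 libraries) and Uncx (chromosome 5, 139530414 to 139570031). Hoxd13 on chromosome 2 starts at 74668225 and had H3K27me3 of 6.40 and 6.58, RING1B of 23.9 and 33.4 and CBX8 of 41.0 and 41.2.

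**Figure D4:**
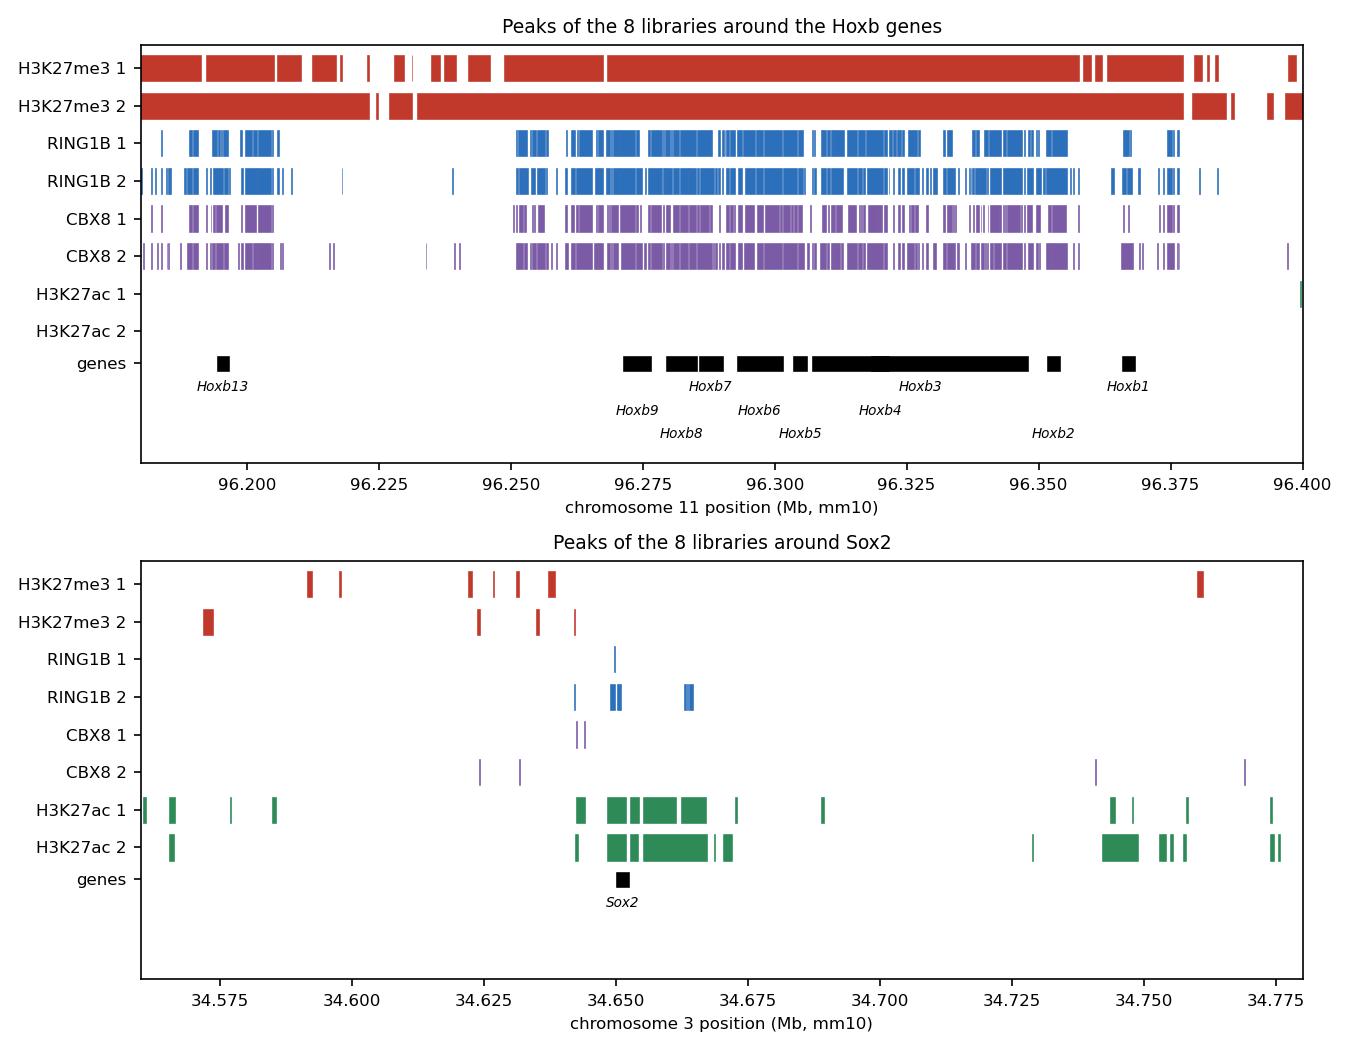
Peaks of the 8 libraries (coloured by antibody, each with its replicate number) along 2 stretches of mm10, around the Hoxb genes on chromosome 11 and around Sox2 on chromosome 3; black boxes are genes of the background. H3K27me3, RING1B and CBX8 cover the Hoxb genes, where H3K27ac has 1 peak at the edge in replicate 1, and H3K27ac has 15 and 14 peaks around Sox2.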

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

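Peaks on chromosome Y were left out of every comparison, and 6 of the 8 lists held more than 3 of them outside the pseudoautosomal end, the level above which a list was picked out. CBX8 replicate 2 held 226, H3K27ac replicates 1 and 2 held 64 and 57, H3K27me3 replicate 2 held 9, RING1B replicate 2 held 8 and CBX8 replicate 1 held 4. The sex of the animals behind the lines is not given in the sources used here, and repeats on Y were not examined.

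Of the tests below, the comparison of acetylated promoters on X and autosomes, that of the X share among the strongest peaks, that of all pairs of RING1B and CBX8 libraries and that of added CBX8 peaks with either H3K27me3 list were chosen after the result was seen.

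All 4 antibodies had few peaks on chromosome X. H3K27me3 was at 7.68% of X promoters against 22.7% of autosomal ones (ratio 0.338, 95% interval 0.260 to 0.440), RING1B at 3.99 against 14.4%, CBX8 at 2.66 against 6.12% and H3K27ac at 48.4 against 64.4%. The shortage includes acetylated promoters (ratio 0.752, 95% interval 0.695 to 0.814), so it was not confined to Polycomb targets; this restates the pattern and is no separate test of it. A single copy of X per cell, which lowers the fold over a genome-wide background, may contribute: the 90th percentile of H3K27ac fold at acetylated X promoters was 0.818 of the autosomal value in replicate 1 (95% bootstrap interval 0.777 to 0.902) and 0.726 in replicate 2 (0.698 to 0.822). The value of replicate 1 lay between the range set for this explanation and the level set against it, and that of replicate 2 in the range, with an interval reaching above it; the range was set for both. The share of peaks on X was not lower in the tenth of each list with the highest folds than in the whole list in any of the 8 lists (for example 1.67 against 1.66% for H3K27ac replicate 2 and 2.51 against 1.66% for RING1B replicate 1). Both shares were taken among called peaks, which a lowered fold also thins, so they do not decide about a halved fold. A single copy of X cannot be told apart from a difference in gene content, because no library with a known number of X copies is in hand, and no biological explanation was tested.

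RING1B was present in both replicates at 1083 of 9275 acetylated promoters without H3K27me3 in either replicate. In lists of equal length, RING1B marked more of these promoters than CBX8. With 9926 peaks each from the same culture, RING1B replicate 2 marked 9.99 times as many as CBX8 replicate 1 (95% interval 8.75 to 11.4). Over all pairs of a RING1B and a CBX8 library cut to equal length, the ratio was 8.24 to 17.2. This does not exclude recovery of open chromatin by any antibody. The promoters were chosen without H3K27me3, which 78.0% of the CBX8 regions overlapped, so lists cut by fold favour a low CBX8 count. In full lists, CBX8 replicate 2, the longest of these, marked 16.2% of the promoters, RING1B replicates 1 and 2 marked 12.4 and 61.7% and CBX8 replicate 1 marked 2.61%. Recovery that grows with acetylation stays open, since the share with RING1B was 15.3% in the third with the highest H3K27ac fold and 8.51% in the lowest (ratio 1.80, 95% interval 1.56 to 2.08), short of the ratio of 2 set for it. RING1B in complexes without CBX8 is a biological candidate that these antibodies leave untested.

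CBX8 replicate 2 held 7.80 times as many peaks as replicate 1. The 72716 added peaks overlapped H3K27me3 regions in 14.5% of cases, 4.74 times the share at shifted positions, above the level set beforehand against background peaks alone. They overlapped H3K27ac regions in 14.9% of cases, 2.73 times the shifted share. Shifts do not keep a preference for genes or open chromatin, so these ratios cannot decide about background peaks. A lower calling limit for the same Polycomb regions stays open. In H3K27me3 regions of both replicates or RING1B replicate 2 peaks lay 18.1% of the added peaks (95% Wilson interval 17.8 to 18.3), under the 25% set beforehand, but that limit left out regions found in a single H3K27me3 list: with peaks of either H3K27me3 replicate counted the share was 32.3% (32.0 to 32.7). A mixture of weak Polycomb sites and other peaks may remain, as may a difference between lines 2 and 3, which the 2 libraries cannot separate from the library itself.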

How the results depend on the processing

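Of 172 values under alternatives, 156 kept their direction and their side of the threshold or moved by less than 1.5 times (for peaks at promoters, by less than the spread between replicates). This count includes values that could not move, because each library was left out in turn also where a result does not use its antibody. The H3K27ac share of H3K27me3 regions, for example, stayed at 2.96% when RING1B or CBX8 replicates were left out. The alternatives chosen after seeing the data were genes without a strand, the authors' annotation, all named transcript starts, and removal of regions listed in all 8 libraries. The H3K27ac share of PRC1 regions (10.4%) fell below its shifted value with stricter peaks (4.27%) and, past the threshold, without the regions listed in all 8 libraries (3.37%), which takes out regions holding both by construction, and lost its p when 50% had to be covered (5.81%); the cause was otherwise not tested. With the nearest gene at any distance, PRC1 targets numbered 1779, their H3K27ac share turned (80.8% against 77.8%), and 11 lists passed for PRC1 and 1 for H3K27ac; assigning distant peaks to genes is part of that rule. RING1B alone gave 2694 targets. Leaving out each library in turn gave 818 to 1476 PRC1 targets, the highest without CBX8 replicate 1. H3K27me3 lists fell from 15 to 9 with stricter peaks, which left 805 and 2051 peaks, and H3K27ac lists from 5 to 3 with the authors' annotation. Peaks at promoters moved with the window by construction: 12.1 and 25.3% for H3K27ac and 6.58 and 17.9% for H3K27me3 at 500 bp and 5 kb, and 39.4% for RING1B at 500 bp. The H3K27me3 share of PRC1 targets was above that of other genes under each of its 16 alternatives (49.5 to 96.3%), the lowest with stricter peaks. Among these alternatives, leaving out H3K27ac libraries could not move it. No paired analysis was possible because a replicate number does not mark the same culture across antibodies, so single libraries were compared instead. For those of 1 culture, CBX8 replicate 1 overlapped 13.2% of RING1B replicate 2, H3K27me3 replicate 1 65.2% of RING1B replicate 1 and H3K27ac replicate 2 19.9% of CBX8 replicate 2; of 2 cultures, the shares were 60.1% (RING1B replicate 1 with CBX8 replicate 2), 37.4% (RING1B and H3K27me3, replicate 2) and 31.3% (CBX8 and H3K27ac, replicate 1), each above shifted positions and between lists of unequal length. Depth is unknown, so a missing peak may reflect a shallow library: CBX8 replicate 1 missed Kit, and 1476 genes qualified without it.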

Other observations

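Of the observations here, the tests of potassium channel genes and of the number of neighbouring methylated olfactory receptor genes were chosen after the result was seen.

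Potassium channel genes formed a large methylated family. H3K27me3 was at 74 of 91 Kcn promoters (81.3%), against 21.9% of the other genes (odds ratio 15.5, 95% interval 9.15 to 26.3, two-sided Fisher's exact test). The family was chosen after its methylation was seen, so these values describe it and are no separate test. The highest folds in the weaker replicate were at Kcna1 (5.12 and 5.27), Kcng3 (5.09 and 5.24), Kcnma1 (5.47 and 4.78), Kcna3 (5.05 and 4.74), Kcnk9 (4.72 and 5.16) and Kcnn1 (4.70 and 5.13). PRC1 was at 15 of the 91 and H3K27ac at 24. The 220 promoters with RING1B, CBX8, H3K27me3 and H3K27ac in all replicates included, beside Bmi1 and Cbx8, the cyclin gene Ccnd2 (RING1B 24.4 and 51.2, H3K27ac 8.90 and 10.3), the nuclear receptor gene Nr4a3 (H3K27ac 9.70 and 10.6), Dock1 (H3K27ac 9.75 and 11.1), Wrap73 (H3K27ac 11.9 and 13.7) and Ankrd34a (H3K27ac 11.8 and 9.92). Peak lists of pooled cells do not show whether both marks lay on the same chromatin. At Ccnd2 the CBX8 fold was 52.4 in replicate 1 and 5.89 in replicate 2.

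Of the 64 methylated olfactory receptor genes, 47 were next to another methylated receptor gene in the order of measured ones and 17 were not. On chromosome 1 all 8 receptor genes from Olfr1416 (start 92480619) to Olfr12 (start 92619881) had H3K27me3, and on chromosome 15 there were 7 in a row from Olfr286 (start 98234450) to Olfr279 (start 98497474), where 8 of 9 measured receptor genes were methylated. Chromosome 11 held 20 of the 64, among 71 measured. RING1B was at none of the 536 receptor promoters in both replicates and CBX8 at 1. When the marked genes were reassigned within chromosomes, 34 pairs of neighbours were marked at both promoters, against a mean of 17.6 in 10000 reassignments (permutation p = 0.0001, the smallest they can give). Counting only neighbours within 1 Mb, which takes out a pair far apart on chromosome 11, left 33 pairs against a mean of 16.8 (permutation p = 0.0001). These counts describe the runs they were chosen from and do not show what makes them. Single listed peaks accounted for few of the pairs. In 1 of the 34 (2.94%, 95% Wilson interval 0.521 to 14.9) the same H3K27me3 peak touched both promoter windows in either replicate, under the level set before this count. The windows lay apart in all 34 pairs, and the median H3K27me3 peak width was 681 and 885 bp. A low count was therefore likely beforehand and says nothing about wider domains that are listed as several peaks. Domains made of several peaks stay open, and 570 receptor genes had no strand and were not counted.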
